A study of Homo sapiens with 4 samples.

How the data were processed

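Total RNA of NALM6 cells was sequenced as 4 libraries, 2 with vehicle and 2 with AICAR. Per the labels' protocols, RNA was extracted with the RNeasy Plus kit, libraries were made with a stranded total RNA kit, and single reads of 75 bases were sequenced on a NextSeq 500. The submitters' processing notes name Trimmomatic 0.32, STAR 2.5.3a, RSEM 1.2.31, DESeq2 and the hg19 build, without their order or settings. The annotation used is not given in the sources used here.

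The authors deposited a table of 20665 genes with a biotype for each. Its expected counts (deposited as estimated counts per gene and library, not normalized) were the values analysed. The deposited FPKM values, normalized by the authors for length and depth, were not tested. The log2 fold changes and q-values in the authors' deposited table are their own comparison, taken from it only for the count of calls and their overlap with the calls made here. All columns were assigned to libraries by their names.

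Groups followed the labels. Expected counts were rounded to whole numbers. Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total 15), libraries were scaled with TMM factors, and the groups were compared with edgeR's two-sided quasi-likelihood test (edgeR 4.0.16, R 4.3.3), with Benjamini-Hochberg adjustment over the 13626 genes tested and a threshold of 0.05. CPM values are scaled by the TMM factors, and means are given with the SD of 2 libraries. No replicate block was used, since nothing in the labels says that a replicate number marks a shared culture or day. The test, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except the fit to protein-coding genes alone, which was added afterwards.

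The 31 gene lists came from textbook knowledge. The 28 lists with at least 5 tested members were tested with limma's camera (limma 3.58.1) on voom values with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists, and also with an estimated correlation and with fry. The genes named are the 12 largest rises and 12 largest falls among changed genes with a mean of at least 10 CPM whose AICAR values both lie on the same side of both vehicle values, leaving out small RNA, clone-named and antisense genes and pseudogenes (80 higher and 49 lower were left out), then in each list the 2 highest and 2 lowest changed members, and a few genes by name. Some other list members are given as examples and were chosen after their values were seen: DUSP6, NFKB1, the ZFP36 genes and, in the immediate early list, any member.

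Depth was 32318376 to 36769116 counts per library. RN7SL1, RN7SK and RN7SL2 took 14.95% to 16.5% of them, and protein-coding genes 77.42% to 79.47%. The replicates of a group differed by more than sampling noise, with a chi-square per gene of 3.887 for vehicle and 2.36 for AICAR, against 39.33 and 45.75 between the groups, so no library was treated as a second copy of another. This does not show that they came from separate cultures. The common biological coefficient of variation was 3.63%. Bounds against a count of 0 use a floor of 3 counts per library and cover counting error only.

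The procedure was tested on 10 simulated sets with the real means and library sizes, with 13442 genes and 200 of them changed. It recovered 61.6% of genes changed 1.3-fold, 71.0% at 1.5-fold, 83.8% at 2-fold and 96.6% at 4-fold, and 10.8% of its calls were false, above the 5% that the threshold aims at. In the data 39.1% of tested genes were called, a far larger share than was simulated. The recovered and false shares depend on that share, so they do not carry over to the real calls.

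The alternatives were other scalings (RLE, upper quartile, total counts alone), no filter or a stricter one, limma-voom, limma on log2(CPM + 1), DESeq2 1.42.0, a replicate block, a stricter threshold, protein-coding genes alone, and leaving out each library in turn. Transcript length, GC content and 3' UTR sequence came from GENCODE 29, matched by gene identifier for 97.2% of the tested protein-coding genes. That annotation is on GRCh38 and not on the authors' build, so no coordinates are given. Trends on length and GC content were removed with a loess fit (span 0.5). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.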

Results

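RNA of NALM6 cells, an established human line of B cell precursor acute lymphoblastic leukemia, was sequenced in 4 libraries. In 2 libraries the cells had received the solvent DMSO for 45 min (vehicle). In the other 2 the cells had been kept without glucose for 24 h and then received 15 mM AICAR for 45 min. AICAR is a nucleoside that cells convert into a mimic of AMP, which activates the energy sensor AMPK. The labels give the glucose-free period for the AICAR libraries only and do not say whether the vehicle cells were also kept without glucose. If they were not, each difference is that of AICAR together with glucose deprivation, and if they were, it is that of AICAR in deprived cells. The vehicle libraries held 33919915 and 36769116 expected counts and the AICAR libraries 32318376 and 34458010. The series title names immediate early genes, which cells induce within minutes of a stimulus without new protein synthesis, and the comparison asks how their transcripts differed between the groups.

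Transcripts of immediate early genes were lower with AICAR. Of 26 tested genes for immediate early transcription factors, 20 fell, 1 rose and 5 did not pass the test. MYC (ENSG00000136997), a transcription factor that drives growth, had 530 ± 18.6 CPM (the count relative to the library's TMM-scaled size) with vehicle and 188 ± 0.636 CPM with AICAR (SD, n = 2), a 2.82-fold fall. IER2 went from 104 ± 0.121 to 22.0 ± 0.285 CPM, and JUNB, a subunit of the AP-1 factor, from 25.1 ± 0.236 to 4.99 ± 0.248 (both SD, n = 2). EGR1 fell 4.0-fold from 9.65 ± 0.652 CPM and FOS 3.10-fold from 1.81 ± 0.32 CPM (SD, n = 2).

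The falls in this list had log2 fold changes of -2.37 for JUN, -2.26 for CSRNP1, -2.18 for KLF6, -1.99 for KLF10, -1.59 for IRF1, -1.34 for ID2 and -0.84 for ID3. SRF, the serum response factor, was the member that rose, by 0.25 on the log2 scale. JUND had a log2 fold change of 0.03 (adjusted p = 0.794, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and FOSB, EGR2, EGR4 and MAFF also did not pass, at means under 1 CPM in both groups, though MAFF was called lower with limma-voom (adjusted p = 0.0453). Adjusted over the list alone, 22 members were lower and 1 higher. The median log2 fold change of the list was -1.54, and limma's camera test with a preset correlation gave an adjusted p of 1.48e-11 over the 28 lists tested. The call was lost in the same test when the correlation between genes was estimated from the data (adjusted p = 0.264 with an estimated correlation).

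**Figure D1:**
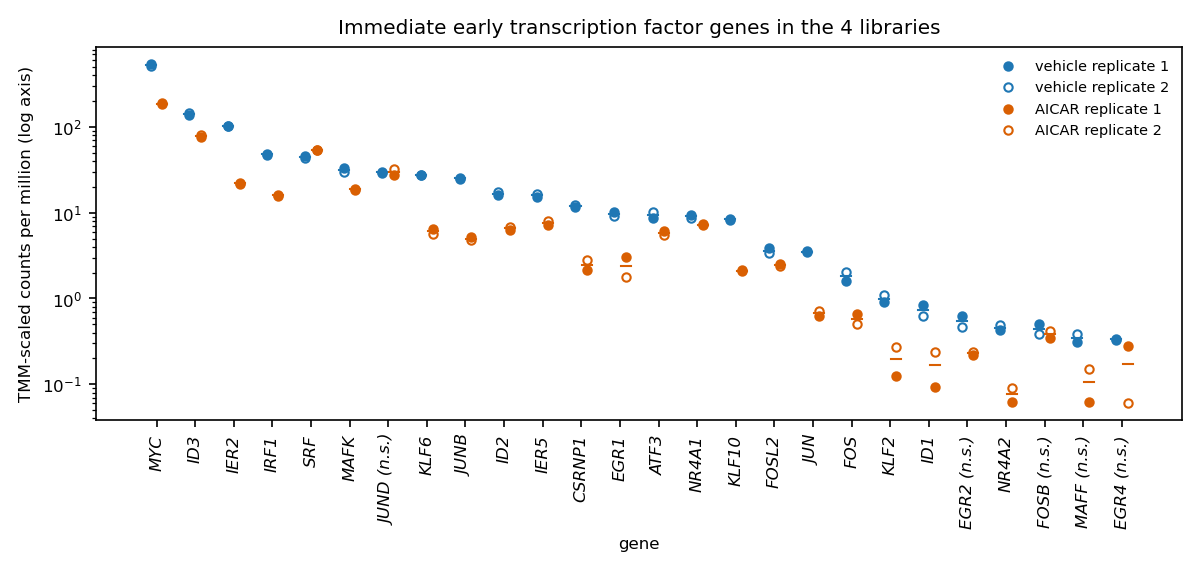
Each point is the TMM-scaled CPM (log axis) of a library, for the 26 tested genes of the immediate early transcription factor list on the x axis; blue is vehicle, orange is AICAR, filled and open points are replicates 1 and 2, short lines are group means, and n.s. marks genes that did not pass the test. MYC lies at 530 CPM with vehicle and 188 with AICAR, and SRF is the changed gene whose AICAR points lie above the vehicle points.

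Other immediate early genes fell as well, 21 of 23 tested with none higher, and the count was the same adjusted over the list alone. CD69, a surface protein of activated lymphocytes, fell 20.9-fold from 6.46 ± 0.481 to 0.304 ± 0.120 CPM (SD, n = 2), and TRIB1, a pseudokinase, fell 7.19-fold. The list includes ZFP36, ZFP36L1 and ZFP36L2, which encode proteins that bind AU-rich elements and promote mRNA decay, with log2 fold changes of -2.52, -1.35 and -2.02. The list's median was -1.18 (camera adjusted p = 8.74e-14, adjusted p = 0.264 with an estimated correlation).

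Feedback genes of the ERK pathway fell in 10 of 15 tested members and 1 rose, as when adjusted over the list alone. DUSP1 (ENSG00000120129), a phosphatase that inactivates MAP kinases, had the largest fall of the genes named by the rule fixed in advance, 23.7-fold, from 101 ± 1.07 to 4.24 ± 0.728 CPM (SD, n = 2), a log2 fold change of -4.56 ± 0.0753 (SE; edgeR adjusted p = 1.85e-11). DUSP2 fell 12.3-fold, and DUSP6 and SPRY2, which restrain ERK signalling, had log2 fold changes of -2.14 and -2.23. ETV5 rose by 0.19, a call that was lost when libraries were scaled by total counts alone, which gave 0.13, and without vehicle replicate 2 (0.15) or AICAR replicate 1 (0.16). The median of the list was -1.16 (camera adjusted p = 1.34e-05, adjusted p = 0.264 with an estimated correlation).

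Among the targets of NF-kB, 7 of 17 tested genes fell and 4 rose. TNF fell 7.20-fold from a low level, 38 and 43 counts with vehicle against 3 and 7 with AICAR, and its log2 fold change of -2.85 was -3.53 without AICAR replicate 2. NFKBIA, the inhibitor that NF-kB induces, fell 4.36-fold, while NFKB1 and NFKBIB, the gene of a second inhibitor, rose by 0.23 and 0.33 on the log2 scale. The list as a whole was not called (median -0.15, camera adjusted p = 0.219), but was called lower without AICAR replicate 2 (adjusted p = 0.0132) and with DESeq2 (0.00614). With total counts alone 2 of its genes rose and 7 fell.

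TXNIP, a glucose-responsive gene that limits glucose uptake, fell 2.83-fold from 62.9 ± 0.504 to 22.2 ± 0.148 CPM (SD, n = 2), and its relative ARRDC4 fell 1.69-fold. In the list of the TXNIP family and FOXO targets, 12 of 17 tested genes fell and 1, the insulin receptor gene INSR, rose. CDKN1B, an inhibitor of cyclin-dependent kinases, fell 3.47-fold and ARRDC3 fell 3.32-fold. The median was -0.53 (camera adjusted p = 1.05e-05, adjusted p = 0.264 with an estimated correlation).

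All 21 tested replication dependent histone genes fell, also when adjusted over the list alone and under each of the 4 scalings tried. HIST1H1D fell 1.95-fold from 1448 ± 44.4 to 742 ± 18.6 CPM and HIST2H2AC 1.98-fold from 572 ± 33.5 to 288 ± 4.76 (SD, n = 2). Histone genes have near-identical copies, so the counts of single members are uncertain. The median was -0.49 (camera adjusted p = 8.58e-17, adjusted p = 0.413 with an estimated correlation). G2/M cell cycle genes fell in 12 of 24 tested members and 2 rose (median -0.09, camera adjusted p = 0.037, adjusted p = 0.388 with an estimated correlation), and the list was also not called without AICAR replicate 2 (adjusted p = 0.112) or with DESeq2 (0.0592). CENPE and HMMR, genes of the mitotic spindle, fell 1.42-fold and 1.37-fold, while the proliferation marker MKI67 rose 1.32-fold.

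Glycolysis genes rose by small amounts, 15 of 20 tested, with 2 lower. HK1, a hexokinase, rose 1.28-fold and TPI1 1.23-fold, while the glucose transporter gene SLC2A1 fell 1.29-fold. The median was 0.19 (camera adjusted p = 1.25e-05, adjusted p = 0.388 with an estimated correlation), and scaling by total counts alone left 10 higher and 2 lower. Of 12 fatty acid synthesis genes, 7 rose and none fell, led by FASN, the fatty acid synthase, at 1.60-fold and the desaturase gene FADS2 at 1.22-fold (median 0.17, camera adjusted p = 0.0065, adjusted p = 0.413 with an estimated correlation). With total counts alone 3 of these rose. All values are relative to the other transcripts of a library. Protein-coding genes with transcripts below 1000 bases had a median of 0.172, and ribosomal protein genes, picked after the values were seen, 0.221. Rises of this size were therefore not particular to these lists or to the ribosome biogenesis and purine lists below.

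Ribosome biogenesis and MYC target genes rose in 17 of 30 tested members and 3 fell, while MYC itself was lower. CAD, an enzyme of pyrimidine synthesis, rose 1.34-fold and RRP12 1.32-fold, while PPAN fell 1.25-fold (median 0.16, camera adjusted p = 0.00574, adjusted p = 0.384 with an estimated correlation). Purine metabolism genes, which include the enzymes that make and use AICAR's phosphorylated form, rose in 9 of 22 tested members and 1 fell. PFAS rose 1.29-fold and APRT 1.26-fold, and PPAT, the first enzyme of purine synthesis, fell 1.13-fold (median 0.07, camera adjusted p = 0.021, adjusted p = 0.388 with an estimated correlation). With total counts alone, 15 rose and 6 fell in the ribosome biogenesis list and 4 rose and 1 fell in the purine list, which was then no longer called (camera adjusted p = 0.0599). With a mean of at least 10 CPM required, neither list was called (adjusted p = 0.0589 for ribosome biogenesis and 0.0909 for purine metabolism).

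The genes of AMPK and its partners showed no common direction, with 2 of 12 tested higher and 4 lower (camera adjusted p = 0.695), or 1 and 6 with total counts alone. PRKAA1, a catalytic subunit, had a log2 fold change of -0.13 (edgeR adjusted p = 0.0652) and did not pass, but was called lower with total counts alone (-0.19), with a mean of at least 10 CPM required (-0.17), without vehicle replicate 1 (-0.17) and in the fit to protein-coding genes alone (-0.13). The subunit gene PRKAB2 and the regulator FNIP1 fell 1.60-fold each, and STK11, the upstream kinase LKB1, rose 1.25-fold. PRKAA2 was not analysed here.

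Of 12 tested genes for protein kinase D, class IIa histone deacetylases and MEF2 factors, 3 rose and 2 fell (camera adjusted p = 0.875). With total counts alone 2 rose and 5 fell, and with RLE or upper-quartile factors 3 rose and 1 fell. HDAC7 rose 1.27-fold, and MEF2B rose 2.41-fold from a low level of 1.16 ± 0.406 CPM (SD, n = 2). HDAC5 rose by 0.20 on the log2 scale, a call that was lost with total counts alone (0.14). HDAC9 had -0.14 (edgeR adjusted p = 0.0489), and was not called without vehicle replicate 2 (-0.12), AICAR replicate 1 (-0.12) or AICAR replicate 2 (-0.16). PRKD2, PRKD3 and HDAC4 had log2 fold changes of 0.17, -0.13 and 0.01 and did not pass. PRKD2 was called higher without vehicle replicate 1 (0.20) or AICAR replicate 1 (0.25), and PRKD3 lower with total counts alone (-0.18), with a mean of at least 10 CPM required (-0.17) and without AICAR replicate 1 (-0.19). PRKD1 was not analysed here.

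The remaining lists were not called by camera in the reported fit. Limma's fry test, which does not compare a list with other genes, called the NF-kB, amino acid response, heat shock, hypoxia, cholesterol synthesis, p53, transcription elongation and interferon response lists as lower and the B lineage, G1/S, lysosome and NRF2 lists as higher (adjusted p from 0.00621 to 0.0486). In the amino acid response list 6 of 24 tested genes rose and 8 fell (adjusted p = 0.308), and the falls included CHAC1, a glutathione-degrading enzyme, at 12-fold and DDIT3, the stress factor CHOP, at 5.87-fold. Of 18 endoplasmic reticulum chaperone genes 8 rose and 4 fell (adjusted p = 0.268), with DNAJB9 4.45-fold lower. With total counts alone 3 rose and 9 fell in the amino acid response list and 4 rose and 4 fell among the chaperones. The amino acid response list was called lower without AICAR replicate 2 (adjusted p = 0.0117) and with DESeq2 (0.0106). Of 14 heat shock genes 5 rose and 6 fell (adjusted p = 0.762), or 3 and 6 with total counts alone. HSPA1B fell 3.21-fold, and shares nearly all its sequence with HSPA1A, so its count is uncertain, while HSP90AB1 rose 1.23-fold. In the hypoxia list none of 17 genes rose and 6 fell (adjusted p = 0.0707), with VEGFA 2.21-fold lower, and with no low-count filter the list was called lower (adjusted p = 0.0348). Of 19 cholesterol synthesis genes 5 rose and 8 fell (adjusted p = 0.505), with LSS, an enzyme of sterol synthesis, 1.22-fold higher.

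B lineage genes rose in 12 of 28 tested members and fell in 6 (adjusted p = 0.125), with the factor TCF3 1.27-fold higher and the recombinase gene RAG1 1.31-fold lower. With total counts alone 5 of them rose and 7 fell, and with no low-count filter the list was called higher (adjusted p = 0.0455). Of 23 G1/S genes 9 rose, MCM5 by 1.25-fold, and 4 fell (adjusted p = 0.0676), or 6 and 4 with total counts alone. This list was called higher without vehicle replicate 1 (adjusted p = 0.0215), with DESeq2 (0.026), with a replicate block (0.0485) and with no low-count filter (0.0165). Of 22 lysosome and autophagy genes 10 rose, CTSD by 1.25-fold, and 3 fell, ATG16L1 by 1.57-fold (adjusted p = 0.0763), or 5 and 3 with total counts alone, and with no low-count filter the list was called higher (adjusted p = 0.036). Of 14 NRF2 targets 8 rose, FTL by 1.25-fold, and 2 fell, MAFG by 1.53-fold (adjusted p = 0.0594). This list was called higher without vehicle replicate 1 (adjusted p = 0.0194) or 2 (0.0315), with DESeq2 (0.017) and with a replicate block (0.0443). Of 21 p53 targets 4 rose and 8 fell, AEN by 1.67-fold (adjusted p = 0.162), or 2 and 8 with total counts alone. Of 22 transcription elongation genes 4 rose, SUPT5H by 1.31-fold, and 9 fell, CLK1 by 1.56-fold (adjusted p = 0.175). Of 19 interferon response genes 3 rose and 4 fell, IFIT5 by 2.20-fold (adjusted p = 0.875), or 2 and 4 with total counts alone. Of 16 genes of mitochondrial biogenesis and fat oxidation 3 rose, POLRMT by 1.28-fold, and 4 fell, NRF1 by 1.35-fold (adjusted p = 0.824). Of 12 BCL2 family genes 1 rose and 2 fell, PMAIP1 by 1.36-fold (adjusted p = 0.961), or 0 and 3 with total counts alone. Of 18 abundant noncoding RNA genes 5 rose, MALAT1 by 1.70-fold, and 8 fell, SNHG1 by 1.66-fold (adjusted p = 0.219), and the list's direction depended on a single library, lower and called without vehicle replicate 1 (adjusted p = 0.00456), higher and not called without vehicle replicate 2 (0.812).

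Among T cell markers 4 were tested and 2 rose, LCK from 28.5 ± 0.510 to 35 ± 0.359 CPM and ZAP70 from 26.7 ± 0.929 to 32.4 ± 2.15 (SD, n = 2). Of the myeloid and erythroid markers CD68 and LYZ were tested, at means under 2 CPM in both groups, and neither passed, though CD68 passed without vehicle replicate 1 (log2 fold change 1.69 in place of 0.98) and without AICAR replicate 2 (1.48). Genes encoded by mitochondrial DNA were not analysed here. Adjusted over the list alone, the AMPK list had 2 higher and 5 lower, the amino acid response list 7 and 8, glycolysis 16 and 2, ribosome biogenesis 18 and 5, B lineage 13 and 6 and G1/S 12 and 4. In the lists given here without such a count, the count adjusted over the list alone equalled that over all genes. The median and the mean differed in sign for the protein kinase D list (-0.05 and 0.10), endoplasmic reticulum chaperones (0.09 and -0.09), mitochondrial biogenesis genes (0.01 and -0.01), interferon response genes (0.00 and -0.08) and BCL2 family genes (0.02 and -0.06).

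**Figure D2:**
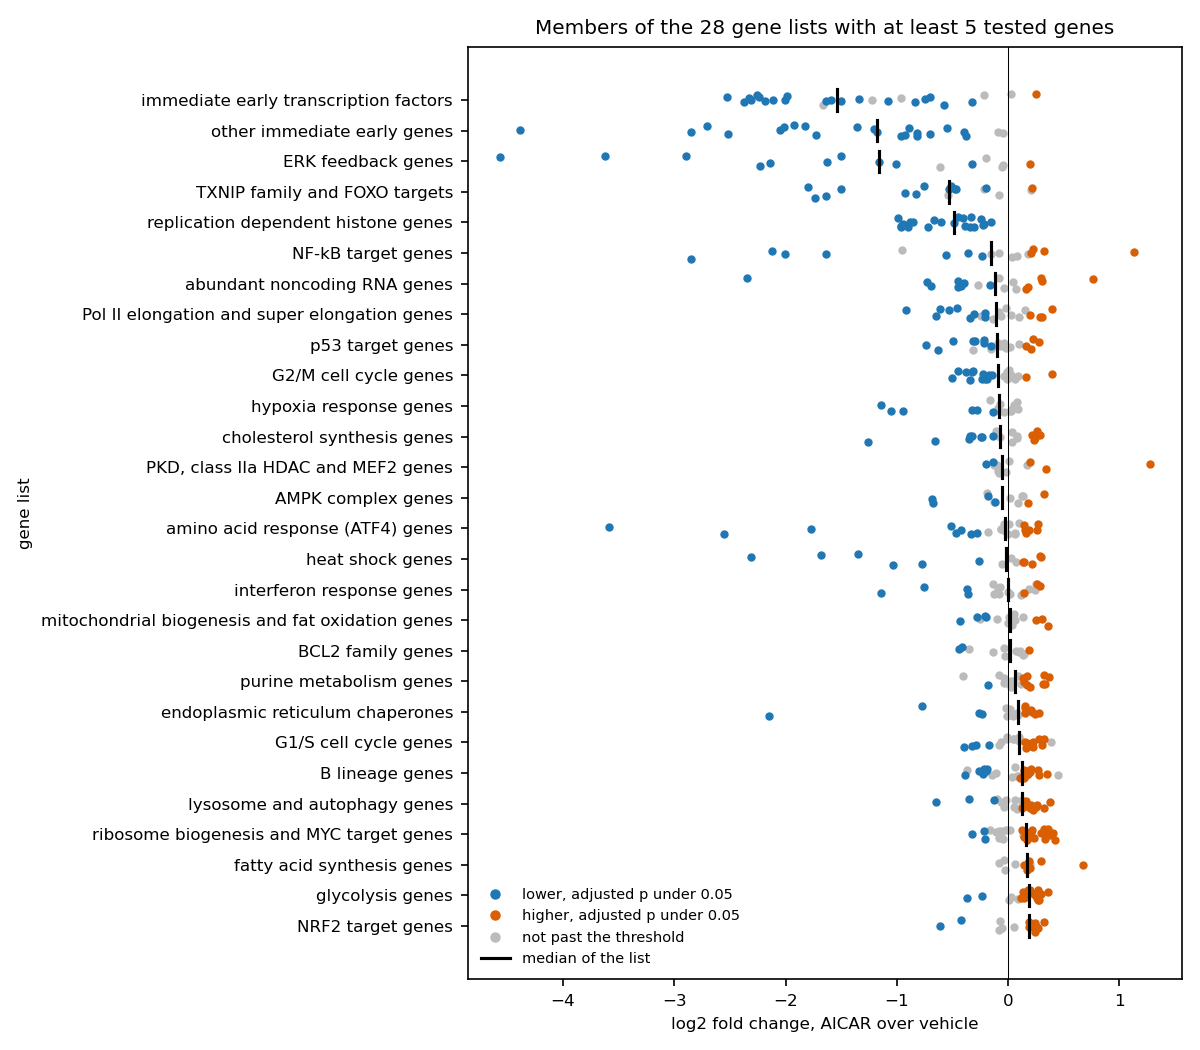
Each point is the log2 fold change, AICAR over vehicle (x axis), of a tested gene in 1 of 28 gene lists (y axis); orange and blue points passed the test as higher or lower, grey points did not, and black ticks are list medians. The immediate early lists lie farthest to the left, with medians of -1.54 and -1.18, and the median farthest to the right is 0.191, that of the NRF2 targets.

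Among the genes with a mean of at least 10 CPM, small RNA genes left out, the largest falls exceeded the largest rises. The falls after DUSP1 were led by CHAC1, RGS16 (10.6-fold), RASD1 (7.45-fold), TRIB1, KCNJ2 (6.74-fold), TBCC (6.06-fold), JUNB, ZNF551 (4.73-fold), IER2, SPRY2 and KLF6. RGS16 and RASD1 act on G protein signalling, KCNJ2 is a potassium channel and TBCC folds tubulin. The largest rise by the same rule was that of TMEM107 (ENSG00000179029), a protein of the ciliary transition zone, at 2.61-fold from 17.0 ± 1.39 to 44.3 ± 1.36 CPM (SD, n = 2). TMEM107 overlaps SNORD118, the U8 small nucleolar RNA gene, on the same strand, so its count is uncertain. It was followed by the dynein gene DYNC1H1 (1.76-fold), the nuclear RNA MALAT1 (1.70-fold), the myosin gene MYH9 (1.65-fold), FASN (1.60-fold), HUWE1 (1.57-fold), HCFC1 (1.56-fold), HNRNPUL2 and CHD3 (both 1.49-fold), FLNA (1.48-fold), MDN1 (1.47-fold) and RNF213 (1.46-fold).

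**Figure D3:**
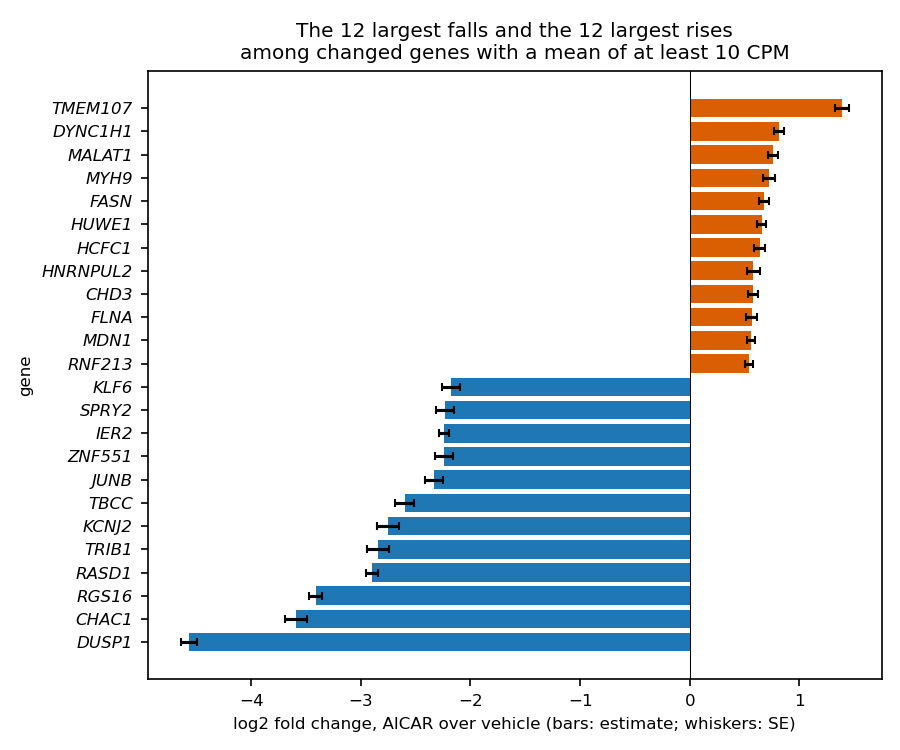
Bars give the log2 fold change, AICAR over vehicle (x axis), and whiskers its standard error, for the 12 largest falls (blue) and the 12 largest rises (orange) among changed genes with a mean of at least 10 CPM. The falls run from -4.56 for DUSP1 to -2.18 for KLF6 and the rises from 1.38 for TMEM107 to 0.54 for RNF213.

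In all, 5328 of 13626 tested genes changed (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 2645 higher and 2683 lower. Of these, 545 changed at least 2-fold, 59 higher and 486 lower, and at least 4-fold changes numbered 16 and 109. Of 11444 protein-coding genes tested, 2485 were higher and 2445 lower. With libraries scaled by total counts alone, 1390 genes were higher and 3135 lower, so 69.3% of the calls were lower in place of 50.4%. The 4 values of a gene did not overlap between the groups for 9424 genes, where chance gives 33.3% of genes. The authors' deposited table holds 3263 genes with a q-value under 0.05, 1677 higher and 1586 lower, and 3252 of them were also called here, each in the same direction.

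The labels do not say whether the replicates were separate cultures, so edgeR's p-values measure the spread between these libraries, which may be technical. Camera compares the genes of a list with the other genes, and the permutation test shuffles genes. Their p-values therefore do not measure the spread between cultures either. DESeq2 run on the same counts called 3267 genes, 1679 higher and 1588 lower.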

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

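The fit to protein-coding genes alone was chosen only after the results were seen, and the other alternatives were planned. The immediate early list was lower under every alternative. No named gene changed direction where it was called in the reported fit or in the alternative. A change of sign between values that were both not called was not counted as a reversal. Among lists that camera did not call, the direction turned for the BCL2 family, protein kinase D, heat shock and abundant noncoding RNA lists under some alternatives, without a call. The counts that moved by over 1.5 times were 1390 genes higher with total counts only, 123 genes changed at least 2-fold with a mean of at least 10 CPM required, 250 changed at least 2-fold with limma on log2(CPM + 1), which shrinks the changes of low genes by its pseudocount, 1727 genes higher at an adjusted p under 0.01, and 3267 changed, 1679 higher and 1588 lower with DESeq2. The stricter filter tested fewer genes, 8231, and for the other counts the cause was not tested. DESeq2 shared 3256 of its calls with the main result, all in the same direction. The immediate early set test gave an adjusted p of 0.264 with an estimated correlation and was no longer called, against 7.46e-12 with a replicate block and 1.48e-11 as reported. Camera called 10 lists, none (0) with an estimated correlation, and fry 22. The estimates lay below the preset 0.01 for the immediate early transcription factor (0.00482), ERK feedback (-0.0547), TXNIP (-0.0196), purine (-0.00996), ribosome biogenesis (-0.0133) and G2/M (-0.0197) lists. For these, a higher correlation was not what removed the call. The estimates lay above it for the other immediate early (0.0823), glycolysis (0.109), fatty acid synthesis (0.226) and histone (0.865) lists. A simulated 2-fold fall of the immediate early list gave an adjusted p of 3.47e-118 with the preset correlation and 0.0415 with an estimated one. The simulated genes were drawn independently, so camera with an estimated correlation was far weaker there even without correlated genes. A call lost with it therefore does not show that a list was unchanged.

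Leaving out 1 library in turn gave 4368 to 5259 changed genes, 2033 to 2616 higher, 2335 to 2643 lower and 556 to 596 changed at least 2-fold, with the lone library of a group assumed to vary like the other group. The immediate early set test then gave 6.22e-27 to 2.97e-15, and 10 to 13 lists were called. Of 149 named genes 7 to 12 lost their call, as did 19 of 141 with DESeq2, 15 with no low-count filter and 8 with total counts only. With replicate number as a replicate block, 5429 genes changed, 2708 higher and 2721 lower, 553 at least 2-fold, and 12 lists were called. Same-numbered libraries did not deviate together (Pearson's r -0.0478 and Spearman's rho 0.0126, across genes), so the numbers were not taken to pair the samples. The alternatives for values without counts were not run, since the table holds counts.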

Other observations

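The tests of library scaling, of AU-rich elements beyond a GC trend, of the small RNA genes, of ribosomal protein genes and of zinc finger genes were chosen only after the results they bear on were seen. The tests of GC content and length on the immediate early list, of AU-rich elements in general and of the slope on length were written down before their results.

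Ribosomal protein genes, a group picked after the values were seen, were higher in 78 of 84 and lower in 2, with a median log2 fold change of 0.22, and 67 were higher with total counts only. Genes of the ZNF zinc finger family, mostly repressors of transcription, moved the other way. Of 392 with a matched annotation, 280 were lower, 109 of them at least 2-fold, and 10 were higher. Calls as lower made up 71.4% of these genes against 19.4% of the other protein-coding genes. Under each of the 4 scalings at least 288 of 403 tested ZNF genes were lower. ZNF799 and ZNF443, chosen after their values were seen, had log2 fold changes of -2.69 and -2.52.

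Small noncoding RNA genes, also chosen after their values were seen, moved in both directions. RNU12, the U12 RNA of the minor spliceosome, had 321 and 416 counts with vehicle and 2415 and 2607 with AICAR, a 7.52-fold rise, and RNU11 rose 1.79-fold. SNORD3D, a copy of the U3 RNA gene, rose 12.6-fold and SNORD3B-2 rose 2.06-fold. RNU5A-1 and RNU5B-1 fell, with log2 fold changes of -2.35 (-2.93 without AICAR replicate 1) and -2.62, and RNU4-1 and RNU1-1 had -0.42 and -0.45. RNU5B-1 had 129 and 166 counts with vehicle and 32 and 11 with AICAR, so the size of its fall also differed between the AICAR libraries. SNORD118 had 44 and 28 counts with vehicle and 0 in both AICAR libraries, which is at least 10.9-fold lower against a floor of 3 counts per library. MTATP6P1, annotated as a pseudogene and not as a small RNA gene, rose 1.88-fold. RNU1-1, RNU4-1, RNU5A-1, RNU5B-1, SNORD3D and SNORD3B-2 belong to gene families with similar copies, so reads can be exchanged between a gene and its copies. For RNU12, RNU11, SNORD118 and MTATP6P1, reads shared with similar sequences elsewhere in the genome were not tested.

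The fall of the immediate early list was weighed against technical explanations. The choice among the 4 scalings did not account for it, since the highest median of the list over them was -1.53. The other scalings shifted the log2 fold changes by a median of only -0.0598 to 0.00781. They could not have brought the list near 0, so their agreement is no independent support. Removing a trend on GC content and length left the list's median at -1.59 (bootstrap SD 0.273). A candidate explanation is a general loss of transcripts with AU-rich elements: outside the lists of induced genes, 3740 genes with TATTTAT in the 3' UTR lay lower than 6861 without by -0.104, matched on UTR length and expression (p = 0.000999, the smallest that 1000 permutations can give). The ZNF genes, 71.4% of them called lower, were not left out of this comparison, so their part in the difference is not known. After the GC and length trend was removed the difference was -0.0419 (permutation SD 0.00798), inside the bound of -0.05 by about 1 SD, so the size set for this explanation was narrowly not reached beyond a trend on GC content, a smaller loss stays open, and at either size the difference is small beside the list's median of -1.54. AICAR remains open as a biological explanation, as does glucose deprivation unless the vehicle cells were also deprived, which the labels do not say.

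The rises of RNU12, SNORD3D and TMEM107 were weighed next. A general rise of genes annotated as small nuclear RNA is argued against by their median of -0.453 over 27 tested genes, 6 higher and 17 lower. RNU12, RNU11 and SNORD3D are annotated as long noncoding RNA and TMEM107 as protein-coding, so none of them is among those genes. This median therefore does not bear on the rises of SNORD3D and TMEM107. TMEM107 gained 27.2 times the CPM that SNORD118 lost. SNORD118 had a mean of only 1 CPM with vehicle, so the reads counted for it could not supply the gain. That outcome was fixed by counts already seen. Reads of SNORD118 counted under TMEM107 in both groups stay open as a cause. For SNORD3D, the summed CPM of the 4 other U3 genes had a log2 ratio of 0.395, within the largest difference between replicates of 0.734, so reads shared between U3 copies cannot be told apart from a rise of SNORD3D. Longer unprocessed forms of these RNAs could give the same picture, which needs read positions that were not used here.

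For the ZNF genes, expression level alone is argued against by their median of -0.611, below the lowest of 10000 random lists matched on expression (-0.142). Removing a trend on GC content and length left the median at -0.558 (bootstrap SD 0.0337). Reads shared between family members were not tested and stay open, as do AICAR and, unless the vehicle cells were also deprived, the lack of glucose.

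A further idea, that long mRNAs rose in general, came from the 12 largest rises, whose median transcript length was 8565 bases against 3390 for all protein-coding genes. It did not hold. Median log2 fold changes were 0.17 below 1000 bases, -0.05 from 4000 to 8000 and -0.02 above, and the short ribosomal protein mRNAs had a median of 0.221, which argues against a bias of the AICAR libraries towards long transcripts. The slope on length between the groups was 1.74 times the larger slope between replicates, under the bound of 3 set beforehand. That bound was set for a rise of long mRNAs. The group slope compares means of 2 libraries and the replicate slopes single libraries, which vary more, so the ratio leans towards chance. The trend ran towards short mRNAs, with 46.7% called higher and 7.86% lower below 1000 bases, against 15.4% and 27.6% from 4000 to 8000. Chance differences in length bias between libraries stay open for this trend and cannot be told apart here.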
